A study of Mus musculus with 80 samples.

How the data were processed

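The series measured RNA of germ cells from mouse testes at postnatal day 5.5. The cells carried a transgene that places green fluorescent protein under Pou5f1 (Oct4) regulatory sequence, and were sorted on that fluorescence. Per the labels' protocols, 71 Oct4-GFP positive, KIT negative cells were captured singly on a Fluidigm C1 machine, and RNA of sorted CD87 positive and CD87 negative cells (2 libraries each) was amplified by the Smart-seq2 method. CD87 is the urokinase receptor, encoded by Plaur. The remaining 5 libraries of the series (3 levels of Oct4-GFP and a pair from an Oct4 siRNA experiment) were not analysed here.

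For the sorted cells, the authors deposited TPM values (length-scaled transcript abundance) per gene. They were made with Trim Galore and RSEM on build mm9, per the submitters' processing notes. For the single cells the authors deposited expected counts per gene, made with Trim Galore and Salmon on the same build per those notes. Tool versions and annotation are not given in the sources used here. Each table held 27128 gene rows. The TPM columns summed to between 580440 and 635203 per library, and the row LOC672857 held 23.9% to 31.2% of each sum. TPM keeps no sequencing depth, so the depth of the sorted libraries is unknown. Among the single-cell rows, 22 gene names had been turned into dates by a spreadsheet program. Those rows held at most 0.609% of a cell's counts and were left out. The same table gave a cluster, I to IV, for each cell, and these deposited clusters were used to group cells.

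Gene symbols were used as the tables give them. Of 500 entries in 27 gene lists, 462 matched a symbol directly and 33 matched through an older symbol in a RefSeq gene table of assembly GRCm38.p6, used for names alone. The other 5 matched none. Lyz2 appears in the tables as Lyzs and Cdk1 as Cdc2a. The lists, tests, alternatives and rule for named genes were fixed before the data were examined.

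CD87 positive and negative libraries were compared with limma 3.58.1 in R 4.3.3 on log2(TPM + 1). The empirical Bayes step used a trend, and the test was two-sided with Benjamini-Hochberg adjustment at 0.05. Genes with a TPM of at least 1 in at least 2 libraries entered, which gave 12715 genes. A gene under 1 TPM in both libraries of a group could enter only through the other group, so lists were also tested without the filter, an alternative chosen after the data were seen. A log2 difference on this scale understates the change of low genes. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333, so a model that shares spread across genes was used. Gene lists were tested with camera at a preset correlation of 0.01 over 26 lists with at least 3 tested members, and again with an estimated correlation. The preset test takes its degrees of freedom from the number of genes, the estimated one from the few libraries. The second can therefore give a much higher p without correlated members. Nothing in the labels says that the libraries of a group came from separate animals, so limma p-values measure the spread between these libraries, which may be technical. Camera p-values at the preset correlation set the members of a list against all other genes. Small values there do not show that a list would differ again in other libraries. Data were simulated with the real genes' means and their spreads after the empirical Bayes step (12715 genes, 200 changed). The test recovered 1.5% of 2-fold, 63.0% of 4-fold, 93.5% of 8-fold and 97.0% of 16-fold changes, with 3 to 7 false calls. Both simulated groups had the same spread, unlike the real ones, so these shares need not hold for the real libraries. Changes were planted only above a minimum mean expression, so recovery in genes as low as Plaur was not checked. Camera called 1 of 520 lists in simulated data without an effect. The simulated genes were independent of each other, so this does not check calls on lists with correlated members. In the real libraries the estimated correlation of a list ranged from -0.49 (Leydig) to 0.65 (peritubular myoid). Where it lay above the preset 0.01, correlated members may have contributed to the higher p of the estimated test.

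The 71 cells had between 182584 and 6820422 expected counts (median 1591516) and between 6962 and 13497 genes at an expected count of at least 1. The filters fixed in advance, 2000 genes and 50000 counts, removed no cell. No animal is named for the cells, so they are 1 sample and no p-value was made from them. Shares of cells with an expected count of at least 1 are given with exact Clopper-Pearson 95% intervals, and levels as CPM, the counts scaled to the cell's total. The counts are PCR reads without molecular identifiers, so intervals and limits cover counting error only. CPM is not adjusted for gene length and was compared within a gene. For comparisons between clusters each cell was also thinned to 182150 counts, the total of the shallowest cell after rounding, which takes an expected count of 0.5 or more as 1. Detection at 0.5 was added as an alternative after the data were seen. The difference of a gene list between cells of a cluster and all other cells is the median over its genes of the difference in mean log2(CPM + 1). It is given as a percentile among 10000 random lists matched on mean expression from 16935 genes detected in at least 5 cells. This description of fixed lists by cluster was added after the data were seen. The deposited clusters were made by the authors from these same cells, so differences between them describe the clusters. In a test on simulated values, a shift of 0.5 in 100 genes lay at the percentile 100, and 2 of 40 unshifted lists lay outside the central 95%. Doublets were not called, since 71 cells are too few for a caller.

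Cells were also clustered without the deposited labels. Rounded counts as log2(CPM + 1), 2000 variable genes without Plaur and Pou5f1, 10 principal components and Ward clustering were used, with the number of clusters from 2 to 6 set by the mean silhouette (scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, Python 3.11.15; Leiden clustering as an alternative with leidenalg 0.10.2). The genes to compare with the sorted libraries were to be those called in a direction. With fewer than 10 called, the 100 with the largest change in each direction and non-overlapping libraries were taken, as fixed in advance, of which 79 higher and 86 lower genes could be used. This gene comparison was fixed for the clusters made here, and its use on the deposited clusters was added after the data were seen.

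The rule for named genes took Plaur and Pou5f1, then up to 12 genes per direction. Genes past the threshold came first, then those with the smallest p, with a mean TPM of at least 5 in the higher group and non-overlapping libraries. In each list it took the members past the threshold up to 4, or the 2 with the smallest p. For single cells it took Plaur, Pou5f1, Kit, Ddx4, the 4 members of each list detected in most cells, and the 10 genes per cluster with the largest fold. Other genes named here (list members such as Ret, Gfra1, Id4, Kit and Dusp6 in the sorted libraries, and Etv5, Gfra1, Tcl1, Ccnd2, Rarg, Upp1, Klf4 and the macrophage genes in the cells) were chosen after their values were seen. Alternatives covered the pseudocount, the filter, scaling, the variance model, a replicate block, each library left out, cell depth, the detection threshold and clustering settings. Figures were drawn with matplotlib 3.10.9.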

Results

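Transcriptomes of neonatal mouse male germ cells were compared in 2 ways: between sorted cells with and without the urokinase receptor CD87 (2 libraries each), and across 71 single Oct4-GFP positive, KIT negative cells. The sorted libraries listed 15579 and 15147 genes above 0 TPM in the CD87 negative group and 16267 and 12063 in the CD87 positive group. CD87 positive library 2 thus stood apart with the fewest genes. The standard deviation of the log2 difference between libraries of a group was 0.631 for the CD87 negative and 1.09 for the CD87 positive pair. On log2(TPM + 1), CD87 positive library 1 had Pearson correlations of 0.943 and 0.939 with the CD87 negative libraries. Its correlation with CD87 positive library 2 was 0.869, so on this measure the libraries did not group by CD87 status.

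The first question was which genes differ between CD87 positive and CD87 negative germ cells. Of 12715 genes tested, 3 rose and 0 fell in CD87 positive cells (limma, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were 428 higher and 201 lower genes. Apoe, which encodes a lipid carrier abundant in macrophages, rose from 4.38 ± 0.14 to 159 ± 43.7 TPM (SD, n = 2 libraries per group; log2 difference 4.86, limma adjusted p = 0.0034). Lyz2, the lysozyme of macrophages and granulocytes, was listed at 0 in both CD87 negative libraries and at 62.1 and 41.5 TPM in the CD87 positive ones (limma adjusted p = 0.0128). Tmsb4x, which encodes an actin-binding peptide, rose from 3.88 ± 0.65 to 58.7 ± 1.13 TPM (log2 difference 3.62, limma adjusted p = 0.0237). None of the 3 calls held when any 1 of the 4 libraries was left out, and with no trend in the variance model 0 genes passed.

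Plaur itself was listed at 0.46 and 0.97 TPM in the CD87 negative and at 3.53 and 8.92 TPM in the CD87 positive libraries (log2 difference 1.98, limma adjusted p = 0.863). Pou5f1 was at 18.3 and 59.04 TPM against 47.4 and 46.5 TPM (log2 difference 0.49, limma adjusted p = 0.885), and without CD87 negative library 1 its log2 difference was -0.32. Other genes with the smallest p in the higher direction did not pass. They were Tcl1 (log2 difference 3.10), the microglial and macrophage adaptor Tyrobp, the complement genes C1qa and C1qb, the selenoprotein gene Sepp1 (3.62), Ccnd2 (1.46), the small RNA row Rn4.5s and the predicted loci LOC100040647 and LOC100039592. In the lower direction the genes with the smallest p, none passing, included Ndrg4 (-1.66), Dmrtb1 (-2.42), Cited1 (-2.26), Crabp1 (-1.21), Apoo (-2.91), Gal (-2.52) and Fabp3 (-2.72). The histone genes Hist1h2an, which has near-identical copies, and Hist1h2aa completed that set, with the loci LOC100042515, LOC100040426 and LOC666622.

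The second question was whether groups of genes moved together. Genes of stem cell self-renewal were higher in CD87 positive cells: all 14 tested members were higher in both CD87 positive libraries than in both CD87 negative ones, where chance separates 33.3% of genes in either direction. For 2 of the 14, under 1 TPM in both CD87 negative libraries, the filter on low values itself fixed that separation. Without the filter, 15 of 17 members above 0 were higher, 14 of them in both libraries. The tested members' median log2 difference was 1.31 (camera adjusted p = 2.86e-14, and adjusted p = 0.179 with an estimated correlation of -0.076). That correlation is under the preset 0.01, so the higher p came with fewer degrees of freedom, not with correlated members. None of the 14 passed over all genes, and 8 passed adjusted over the list alone, all higher. Tcl1, an activator of AKT signalling, was at 6.56 ± 0.54 against 68.2 ± 35.2 TPM. The GDNF receptor genes Gfra1 (21.03 ± 0.34 against 53.02 ± 0.15 TPM) and Ret (26.1 ± 5.42 against 66.1 ± 2.40 TPM) and the transcriptional regulator Id4 (10.8 ± 2.28 against 29.6 ± 6.76 TPM) were also among the 8. The list of GDNF and FGF response genes, which shares members with the self-renewal list, had a median of 1.05 (camera adjusted p = 5.41e-09, and adjusted p = 0.186 with an estimated correlation of -0.044). Of its 19 tested members 0 passed over all genes and 8 adjusted over the list alone, all higher. They included Etv5 (14.1 ± 1.13 against 45.2 ± 2.98 TPM), Egr2 (7.16 ± 0.37 against 29.99 ± 6.09 TPM) and the MAP kinase phosphatase gene Dusp6 (6.91 ± 2.28 against 31.5 ± 7.35 TPM).

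Macrophage and leukocyte markers were higher in the same libraries. The 7 tested members had a median log2 difference of 3.71 (camera adjusted p = 1.88e-15, and adjusted p = 0.179 with an estimated correlation of -0.147). Lyz2 passed over all genes and 6 passed adjusted over the list alone. Since 5 of the 7 were under 1 TPM in both CD87 negative libraries, they could enter the test only by being higher in the CD87 positive ones. Without the filter, all 14 members above 0 were higher in mean log2(TPM + 1), 9 of them in both libraries, with a median of 1.98 (camera adjusted p = 1.43e-12, and adjusted p = 0.375 with an estimated correlation). Tyrobp, C1qa and C1qb were listed at 0 in both CD87 negative libraries and between 8.97 and 21.9 TPM in the CD87 positive ones. These markers moved with the self-renewal, GDNF and every other list that was higher in CD87 positive cells.

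Genes of differentiating spermatogonia were lower as a list (13 tested, median log2 difference -0.35, camera adjusted p = 0.0226, and adjusted p = 0.711 with an estimated correlation of 0.164). Over all genes 0 passed, and adjusted over the list alone 2 passed in opposite directions: Dmrtb1, a regulator of the switch from mitosis to meiosis, was lower (32.2 ± 4.57 against 5.82 ± 4.04 TPM), and the cyclin gene Ccnd2 was higher (47.4 ± 4.62 against 132 ± 15.0 TPM). Kit, the receptor that marks differentiation, had 64.3 ± 15.8 against 30.1 ± 10.8 TPM (log2 difference -1.09) and did not pass. The list lost its call without CD87 negative library 2 (median -0.11) and without CD87 positive library 1 (median -0.40), and held without CD87 negative library 1 (median -0.58).

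Proliferation lists were slightly higher in CD87 positive cells. The G2 and M phase list (33 tested) had a median of 0.31 (camera adjusted p = 0.0022, and adjusted p = 0.711 with an estimated correlation of 0.456). The S phase list (30 tested) had a median of 0.29 (camera adjusted p = 0.011, and adjusted p = 0.711 with an estimated correlation of 0.278). No member of either passed over all genes or adjusted over the list alone. Cdk1 (log2 difference 1.10), Nuf2 (0.95), Prim1 (1.34) and Uhrf1 (0.62) had the smallest p. Both calls ended without CD87 positive library 2 (medians 0.16 and 0.21) and without CD87 negative library 1 (0.21 and 0.11), and the S phase call also without CD87 positive library 1 (0.23). Both held without CD87 negative library 2 (0.47 and 0.45), and the G2 and M phase call without CD87 positive library 1 (0.50).

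Immediate early genes were higher as a list (median 0.50, camera adjusted p = 0.0052, and adjusted p = 0.711 with an estimated correlation of 0.337). So were adhesion genes (median 0.30, camera adjusted p = 0.0064, and adjusted p = 0.459 with an estimated correlation of -0.021). Glycolysis genes were also higher (median 0.25, camera adjusted p = 0.025, and adjusted p = 0.711 with an estimated correlation of 0.145). No member of these 3 lists passed over all genes or adjusted over the list alone. Members with the smallest p were Zfp36 (log2 difference 1.53), Dusp1 (1.43), Cdh1 (2.18), Rhoc (1.08), Pdk1 (0.87) and Pkm2 (0.59). The immediate early call ended without CD87 negative library 1 (median 0.016) or CD87 positive library 2 (0.54), and the adhesion call without CD87 negative library 2 (0.29) or CD87 positive library 1 (0.35). The glycolysis call ended without CD87 negative library 1 (0.089) or either CD87 positive library (0.39 and 0.32). Without CD87 negative library 2 the immediate early and glycolysis calls held, with medians of 0.86 and 0.52.

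Markers of other somatic cells moved apart. Sertoli markers were lower in CD87 positive cells (16 tested, median -0.83, camera adjusted p = 0.0022, and adjusted p = 0.711 with an estimated correlation of 0.296). None passed over all genes or adjusted over the list alone, and without CD87 positive library 2 the median was -0.04 and the call ended, while without CD87 positive library 1 it was -1.48. Clu was at 38.9 and 84.1 TPM in the CD87 negative and 34.2 and 1.37 TPM in the CD87 positive libraries, and Inha had a log2 difference of -1.43. Leydig markers, with 3 of 10 members tested, say little: their median of -1.14 was that of Hsd17b3, which entered the test only through the CD87 negative libraries (camera adjusted p = 0.011, and adjusted p = 0.519 with an estimated correlation). Of the 3, 0 passed over all genes and 1, Fabp3, adjusted over the list alone. Fabp3 was also detected in 29 of the single cells, at a median of 0.31 CPM. Peritubular myoid markers were higher (4 tested, median 0.74, camera adjusted p = 0.025, and adjusted p = 0.711 with an estimated correlation of 0.65). Of these 4, 0 passed over all genes and 1, Smoc2, adjusted over the list alone. Smoc2 was also detected in 64 of the single cells, at a median of 84.8 CPM, so its rise need not mark myoid cells. The myoid call ended without the filter on low values (9 members above 0, median 0.32, camera adjusted p = 0.189), and without CD87 positive library 2 (median 0.091) or CD87 negative library 2 (0.93), and held without CD87 positive library 1 (1.49). The Leydig call ended without CD87 negative library 1 (-1.16) or CD87 positive library 1 (-1.14).

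**Figure D1:**
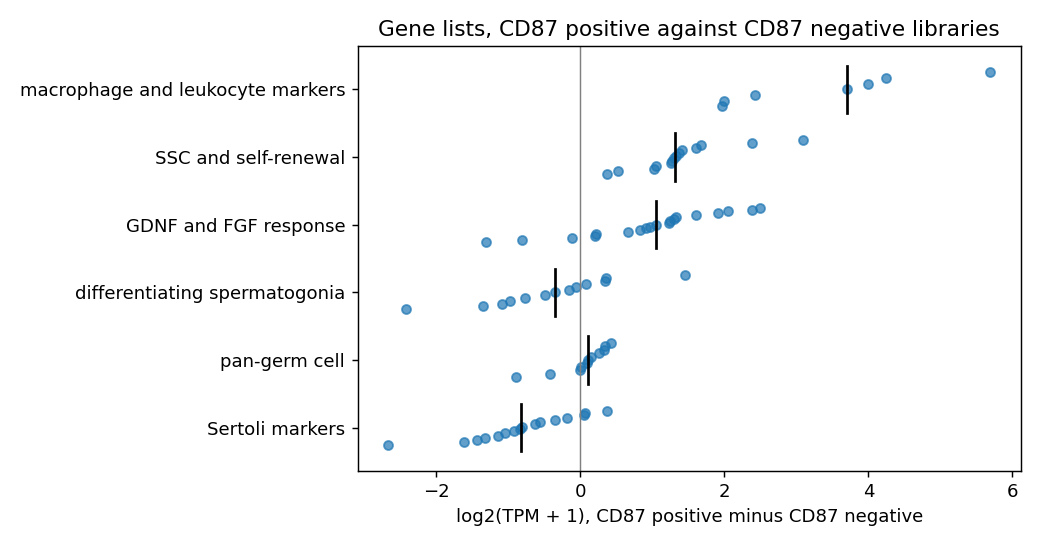
Each point is 1 tested gene of a list fixed in advance, placed by its difference in mean log2(TPM + 1) between 2 CD87 positive and 2 CD87 negative libraries; black bars are list medians and height within a row only separates points. The 14 self-renewal and 7 macrophage genes shown lie to the right of 0, with medians of 1.31 and 3.71, and 2 and 5 of them passed the filter through the CD87 positive libraries alone; the pan-germ median is 0.11.

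The other 14 lists were not called (camera adjusted p from 0.120 to 0.986). Pan-germ cell genes had a median of 0.11 and piRNA pathway genes -0.0021. Progenitor genes (0.043), meiotic genes (0.025), pluripotency genes (0.33, mean 0.0089), WNT (-0.0060), BMP (0.068), p53 (0.032), oxidative phosphorylation (0.076), DNA methylation (-0.28), retinoic acid (-0.23), urokinase system (0.00094), stromal (0.95) and endothelial genes (0.52) made up the rest. Crabp1, a retinoic acid binding protein gene, passed adjusted over its list alone and was lower (186 ± 45.95 against 78.7 ± 1.10 TPM). Erythroid markers had too few tested members for a list test.

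Single cells were examined for which genes individual KIT negative germ cells contained. The germ cell genes Ddx4, Dazl, Sall4 and Zbtb16 were detected in 71 of 71 cells (95% interval 94.9% to 100%), with a median for Ddx4 of 594 CPM (quartiles 471 and 771). Plaur was detected in 30 cells (42.3%, interval 30.6% to 54.6%) at a median of 0.55 CPM (quartiles 0 and 1.93). A further 18 cells had an expected count for Plaur between 0.5 and 1, so that share depends on the cut (67.6% at 0.5, interval 55.5% to 78.2%). Pou5f1 was detected in 57 cells (80.3%, interval 69.1% to 88.8%) at a median of 6.72 CPM. Kit, on whose protein the cells were sorted as negative, was detected in 36 cells (50.7%, interval 38.6% to 62.8%) at a median of 0.81 CPM.

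Among self-renewal genes, Foxo1 was detected in 71, Egr4 in 70, Ret in 68 and Etv5 in 64 cells. Of the meiotic list, 8 of 21 members, among them Smc1b, Tex15, Tex11 and Sycp1, were detected in every cell. Ccnd2 was present in all 71 cells at a median of 1133 CPM. Lyz2 and Tyrobp were each detected in 1 cell, Tmsb4x in 3 and Apoe in 17, and C1qa and C1qb in 0 of 71, which allows a share of cells with a count of up to 4.23% by the limit of 3 counts (exact interval 0% to 5.06%). Cx3cr1 and Nanog were listed in all 71 cells (with a median for Nanog of 354 CPM). Nanog has near-identical pseudogenes, so its level is uncertain. Some listed markers of somatic cells were also detected in most cells: Ctsl in 66, Sox9 and Itgam in 65 and Star in 61. Others were not, such as Wt1 in 11 and Cyp11a1 in 0 cells. A count of at least 1 therefore does not by itself mark a cell type.

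The authors' deposited annotation placed 9 cells in cluster I, 32 in II, 24 in III and 6 in IV. Median totals were 1444836, 1601407, 1681169 and 1121541 counts and median genes 9730, 10894, 10255 and 8806. Self-renewal genes were high in clusters I and II and low in clusters III and IV: against all other cells the list differed by a median log2 of 0.80 in II (percentile 100 of matched random lists) and -1.45 in IV (percentile 0), with 0.47 in I (percentile 100, and 98.2 after thinning) and -0.32 in III (percentile 1.07). In cluster II, differentiating genes differed by 0.52 (percentile 98.96, but 97.2 after thinning, within the central 95%) and immediate early genes by 0.41 (percentile 97.46, within the central 95%, but 98.99 after thinning). GDNF and FGF response genes differed by 0.80 in II (percentile 99.98) and -1.41 in IV (percentile 0.02). Progenitor genes were low in clusters I (-0.74, percentile 1.06) and II (-0.10, percentile 0.37) and high in III (0.26, percentile 98.3). After thinning these percentiles were 0.26, 2.13 and 99.2. In IV the progenitor list differed by 0.041 (percentile 92.0, and 97.0 after thinning, within the central 95%). Thinned to 1 depth, the self-renewal list differed by 0.83 in II and -1.30 in IV, and by 0.20 in I and -0.36 in III. No test across cells was made, since the cells are 1 sample.

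Gfra1 was detected in 0 of 6 cells of cluster IV, against 29 of 32 in cluster II (1 and 30 at a cut of 0.5), and Etv5 was detected in 1 of 6 cells. Ccnd2 had a median of 79.3 CPM in cluster IV against 1272 CPM in cluster II. The retinoic acid receptor gene Rarg was detected in 5 of 6 cluster IV cells (median 71.6 CPM) and in 7 of 32 cells of cluster II (5 and 12 at a cut of 0.5). Klf4 had medians of 180 CPM in IV and 5.57 CPM in II. Plaur was detected in 3 of 9, 19 of 32, 6 of 24 and 2 of 6 cells of clusters I to IV, and after thinning in 2, 13, 3 and 0. At a cut of 0.5 these were 5, 24, 16 and 3 cells, so the contrast between II and III depends on the cut. S phase genes differed by -1.11 in cluster IV (percentile 0) and G2 and M phase genes by 0.59 in cluster II (percentile 100) and -0.77 in cluster I (percentile 0.02). Pan-germ genes differed by -0.03 in cluster IV (percentile 72.7) and -0.63 in cluster I (percentile 1.05).

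**Figure D2:**
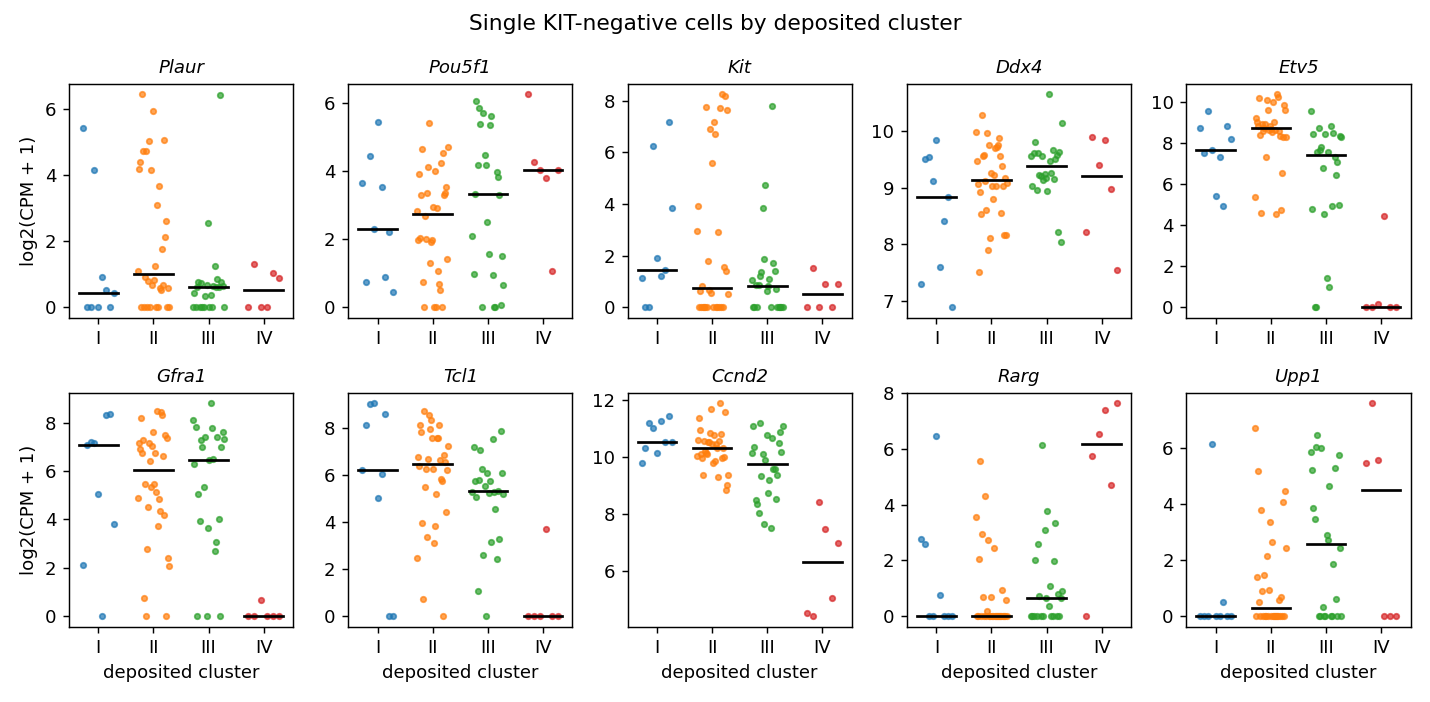
Each point is 1 of the 71 cells, placed by log2(CPM + 1) of the gene above the panel and by deposited cluster (9, 32, 24 and 6 cells); black bars are cluster medians and the vertical axes differ between panels. Etv5, Gfra1, Tcl1 and Ccnd2 are low in cluster IV and Ddx4 is present in every cell.

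Among genes detected in at least 50% of the cells of a deposited cluster, those with the largest fold over the other cells, given as a description and not as results, began with Zfp709, Ercc5 and 1110029E03Rik for I, Galns and Zik1 for II, Leng1, Anks1 and Cbx7 for III, and Dscaml1, LOC667964 and Dbn1 for IV. Several of these folds rested largely on 1 cell, which held 94.2% of the cluster's summed CPM for Zfp709, 62.6% for 1110029E03Rik, 73.3% for Galns, 71.9% for Dscaml1, 95.5% for LOC667964 and 56.2% for Dbn1. Clustering without the deposited labels gave 2 clusters of 55 and 16 cells (silhouette 0.281). The smaller held all 6 cells of cluster IV, 6 of cluster I, 3 of III and 1 of II. Its cells had fewer genes (median 9344 against 10632). The adjusted Rand index with the deposited clusters was 0.263.

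The genes that differed most between sorted CD87 positive and negative cells were then followed across the single cells. Between clusters, the genes higher in CD87 positive cells were higher in deposited cluster II than in IV (median log2 difference 0.54, percentile 99.9) and lay 0.21 above cluster III (percentile 97.2, within the central 95% of matched random lists, and 99.4 after thinning). Clusters I and III lay 0.20 and 0.31 above IV, within that range (percentiles 85.4 and 95.3). They lay outside it after thinning (98.1 and 99.99) and without macrophage genes (98.4 and 98.95). Between clusters I and II they differed by -0.31 (percentile 2.15), and by -0.20 after thinning, at the percentile 19.5 and thus within the range of matched random lists. They were 0.26 higher in the larger than in the smaller of the 2 clusters made here (percentile 98.6), but without macrophage genes by 0.24 (percentile 97.3), within the central 95% of matched random lists. The genes lower in CD87 positive cells lay at percentile 42.9 in that pair. Between deposited clusters II and III they differed by -0.01 (percentile 0.16), which thinning moved to 0.033 (percentile 12.7), within the range of matched random lists. Across 12700 genes, which are not independent replicates, pooled single-cell CPM correlated with mean TPM at a Spearman coefficient of 0.680 for CD87 negative and 0.674 for CD87 positive libraries.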

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

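Leaving out macrophage genes, using the deposited clusters, testing lists without the filter and detection at 0.5 counts were chosen after the data were seen. The 3 genes called between CD87 groups became 1 with a pseudocount of 0.1, 1 with no filter and 0 with no trend (673 at an unadjusted p under 0.05). With each library left out in turn the count was 0 to 0, against 129 to 3706 at an unadjusted p under 0.05; these fits have fewer samples and assume that the lone library varies like the other group. The other 6 settings gave 3. With the group number as a replicate block, 130 genes passed (84 higher), but nothing says that the numbers pair libraries, and the deviations of same-numbered libraries correlated at 0.0675 over 2 pairs. The 12 called lists were 0 with an estimated correlation (3 at an unadjusted p under 0.05), 6 to 9 with a library left out, 11 without the filter on low values, and 12 under the block, the other pseudocount and the other scaling. With a library left out, Pou5f1 ranged from -0.32 (reversed, without CD87 negative library 1) to 1.31, 1700007E06Rik from -0.10 (reversed, without the same library) to 0.99 and Cnn1 from -0.30 (reversed, without CD87 positive library 2) to 2.05. Detection at 5 counts was 22.5% for Plaur, 63.4% for Pou5f1 and 26.8% for Kit, and after thinning 25.4%, 57.7% and 35.2%; the first raises the threshold and the second lowers the counts per cell. At 0.5 counts Plaur was at 67.6% and Kit at 63.4%, since many cells had just under 1 expected count. The cell filters removed no cell. The adjusted Rand index was 0.103 with 1000 variable genes, 0.107 after thinning and 0.141 with Leiden clustering. For the deposited clusters, thinning moved the higher genes to -0.20 (I minus II), 0.30 (I minus IV) and 0.41 (III minus IV), and the lower genes to 0.17 (II minus IV) and, reversed, 0.033 (II minus III). Without macrophage genes I minus IV was 0.29 and III minus IV 0.35 in the higher genes, now outside the central 95% of matched random lists (percentiles 98.4 and 98.95). Two-way changes occurred: I minus II was -0.27 (percentile 9.9), and the larger minus the smaller cluster made here was 0.24, both no longer outside it. Taking the 100 largest changes was already the setting used. With a mean TPM of at least 5 the correlation of pooled cells was 0.466 for CD87 negative and 0.478 for CD87 positive libraries, on fewer genes. Beyond fewer samples, genes or counts, the cause was not tested.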

Other observations

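Of the tests below, that of the second macrophage list was fixed before its values were seen; its version without the filter and all other tests were chosen after the results they bear on were seen.

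Within the single cells, 5 of the 25 lists examined had a median correlation with Plaur above the central 95% of matched random lists, after thinning to 1 depth. They were the GDNF and FGF response (median Spearman coefficient 0.16 over 19 genes), immediate early (0.13 over 17), self-renewal (0.12 over 17), G2 and M phase (0.074 over 33) and macrophage lists (0.19 over 8). Only genes detected in at least 5 cells entered, so the 8 macrophage genes did not include Lyz2, Tyrobp, C1qa or C1qb. Progenitor genes lay at -0.054 and pan-germ genes at -0.067. After thinning, Plaur was detected in a minority of the cells, most of them in cluster II, so these correlations may follow the clusters.

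Macrophage genes were higher in the CD87 positive libraries. A hypothesis is that some macrophage RNA was carried in the sorted fraction. The cells were sorted on Oct4-GFP, and how far that gate kept macrophages out was not measured. A second list without genes of the first gave a median log2 difference of 1.48 over 11 tested members (camera p = 1.66e-05, and p = 0.0457 with an estimated correlation), but the rule set in advance also asked for 80% of them higher in both CD87 positive libraries, and 8 (72.7%) were, all of which the filter had fixed in that direction. So this stays open: without the filter 23 of 24 members were higher, 10 of them in both libraries, with a median of 0.97 (camera p = 4.52e-10, and p = 0.134 with an estimated correlation). Against germ cells as the source of Lyz2, Tyrobp, C1qa and C1qb, the median share of the 30 cells with Plaur that detected them was 0% (1.04% at a cut of 0.5 counts); for Cd68, Fcer1g and Cd14 it was 40% (41.7%), so germ cells may contribute to these and the sources cannot be told apart.

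Self-renewal genes were also higher in the CD87 positive libraries. The low gene number of CD87 positive library 2 was argued against as the whole cause, since the list median without it was 1.33. Less germ cell RNA in the CD87 negative libraries was argued against by the upper quartile of the pan-germ list, 0.29. A hypothesis is that germ cells with more Plaur express more of these genes. The list's median correlation with Plaur in single cells lay at the percentile 99.9 of matched random lists, although 4 other lists also lay above the central 95% and the coefficient was 0.12. After thinning, most cells with Plaur were in cluster II, where self-renewal genes were also high. The correlation cannot tell a link to Plaur from that difference between clusters. Macrophage RNA in the fraction stays open for genes macrophages also express.

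Self-renewal genes were low in cluster IV cells. Lower depth was argued against, since the list stayed at the percentile 0 after thinning. Cells other than germ cells were argued against by Ddx4 and Dazl in 6 of 6 cells, although all 71 cells had both genes. The pan-germ list lay at the percentile 72.7 in cluster IV. That percentile cannot tell germ cells from others, since cluster I, whose cells also had both genes, lay at 1.05. Neither check bears on germ cells of another stage, which stays open. The 6 cells are part of 1 sample and the design names no group for them, so no biological explanation was tested.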
